A study of Musa acuminata AAA Group and Musa AAB Group with 2 samples.

How the data were processed

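Small RNAs were sequenced from 2 banana varieties, with 1 library per variety. The Fusarium wilt-susceptible variety was a Brazilian banana (written Brasilian in the labels) of genotype AAA, and the resistant variety was a plantain of genotype AAB. Each library held leaf and root RNA together, and the labels give no mixing ratio. The plants were kept in culture medium without any labelled inoculation. Per the labels, total RNA was size-fractionated to short RNAs, adapters were ligated, and the PCR products were sequenced by synthesis. The protocol names no molecular identifiers, so reads are not independent molecules.

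The authors deposited, for each library, a table of known miRNAs and a table of predicted miRNAs. The deposited known-miRNA tables give, per row, a read count for a named plant miRNA and a count for its most abundant tag (a distinct read sequence). The same rows carry the authors' RPM, the conventional relative read count, which is the count scaled by a single library total. That total was recovered from the ratio of the columns, and the RPM recomputed from it differed from the deposited RPM by at most 0.00497. The submitters' processing notes list Bowtie 0.12.7. The aligner settings, the miRNA database version, the mismatches allowed, the genome build and the prediction tool are not given in the sources used here. Rows carry the names of miRNAs from 30 species in each library, and 1 read can be counted in several rows.

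The tables are named by sample number alone. They were tied to the varieties by the number that follows the sample name in each library title, and no other entry in the tables checks this link. If the numbers were exchanged, every direction given here would be exchanged too.

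Rows were grouped into families by miRNA number, with miR156 and miR157, and miR165 and miR166, kept apart. A sequence named under both miR156 and miR157 was counted in full in each. The level of a family was the sum over its distinct mature sequences, in RPM of the whole library. Ratios were log2(resistant + 1) minus log2(susceptible + 1), taken over families listed in both libraries whose higher level was at least 10 RPM. A family was called higher in a library where this ratio reached 2-fold. Folds are ratios of the RPM without the added 1. With 1 library per group, no test between varieties was possible and no p-value or SD is given. Intervals are exact 95% intervals (Clopper-Pearson on the split of the counts for ratios and for shares). They cover counting error only, and are too narrow for sums that count a read more than once. A count of 0 was taken to allow up to 3 counts. The library totals were 9000989 reads (susceptible) and 3815454 reads (resistant), so that 1 read was 0.111 and 0.262 RPM and 3 counts were 0.333 and 0.786 RPM.

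Before the data were examined, 6 lists of families were fixed (auxin, developmental transcription factors, nutrient and copper, silencing pathway, NLR-targeting, monocot-restricted). The median ratio of each list with at least 3 families was placed among 10000 random lists of the same size, drawn in 3 bins of mean level. The random lists were drawn from all families at the minimum level, the list's own members included. This percentile describes the 2 libraries and is no test between varieties. Families named by rule were the 8 highest and 8 lowest ratios, the 5 most abundant of each library, up to 5 most abundant listed in 1 library only, and 2 to 4 examples per list. Every predicted miRNA was named as well. Single mature sequences and passenger strands were chosen for description after their values were seen. No row carried a name on the fixed list of animal miRNAs (0 rows in each library).

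The procedure was tested on simulated data with 1000 families. All 100 families simulated with a 4-fold difference and all 100 with a 3-fold difference were called. None of the 800 unchanged families was called (0), and the interval held the true ratio in 95.8% of families. Each simulated family was a single independent Poisson count per library. These values therefore cover counting error alone, and neither reads counted more than once nor a spread between plants. Alternatives fixed in advance were other pseudocounts (0.1 and 10), minimum levels, scalings, family sums and fold limits, merged families, and other ways to match names and sequences. A further 4 alternatives were added after seeing the data. Counting intervals of list medians came from 500 Poisson redraws. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome was used, so no positions are given.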

Results

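Small RNA libraries from a Fusarium wilt-susceptible banana (genotype AAA) and a wilt-resistant plantain (genotype AAB) were compared to find miRNAs whose levels differ between the varieties. Fusarium wilt is a soil-borne fungal disease of banana. Each variety had 1 library of pooled leaf and root, without replicates, so differences are given as sizes with counting intervals and could not be set against a spread between plants. The susceptible library held 9000989 reads and the resistant library 3815454, a depth ratio of 2.36. The known-miRNA tables held 503 and 537 rows, 220 and 232 distinct mature sequences, and 37 and 35 families. Counted once each, the most abundant tags of these rows made up 11.6% and 11.5% of the reads. Tags of 21 nt carried 90.3% and 87.7% of the tag reads. Variety, genotype and library are one and the same split here, and the link between tables and varieties rests on a sample number alone.

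Among 27 families that were listed in both libraries and reached 10 RPM (reads scaled to a common library total), 7 were at least 2-fold higher in the resistant variety, 2 were at least 2-fold higher in the susceptible variety, and 18 lay within 2-fold. The families higher in the resistant variety were miR169, miR395, miR398, miR827, miR408, miR390 and miR399. Those higher in the susceptible variety were miR393 and miR159. The median log2 ratio of the 27 families was 0.22. Centring the ratios on the median of all families listed in both libraries, a shift of 0.20, left 7 families higher in the resistant variety and gave 5 in the susceptible variety, the added ones being miR166, miR168 and miR172.

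Families of the nutrient and copper list were higher in the resistant variety, in 5 of 5 cases at the minimum level. Of these, miR395, miR398 and miR408 reached that level in the resistant library only, so they were eligible through the library where they were high. The sum of miR395, which targets genes of sulfate assimilation, stood at 8.55 RPM in the susceptible and 52.9 RPM in the resistant library (6.19-fold, 95% counting interval 4.74 to 8.16). This sum adds overlapping sequences, so a read can count in several. The highest one, tae-miR395b, had 2.78 and 18.1 RPM (6.51-fold, 4.07 to 10.7). miR827 and miR399, both known from phosphate homeostasis, were 4.60-fold (4.26 to 4.96) and 2.66-fold (2.34 to 3.02) higher, with miR827 going from 114 to 522 RPM and miR399 from 50.7 to 135 RPM between the libraries. The miR399 sequences were not alike. The highest one, osa-miR399j, was 2.92-fold (2.44 to 3.50) and aly-miR399f 6.53-fold (4.25 to 10.3) higher. In contrast, osa-miR399a had 48 and 11 counts, a fold of 0.541 (0.253 to 1.06). miR398 and miR408, which target copper proteins, were near the minimum level, at 12.1 and 14.2 RPM in the resistant library. miR398 had summed counts of 12 in the susceptible and 46 in the resistant library, and miR408 had 27 and 54. Their folds were 9.04 (4.71 to 18.8) and 4.72 (2.92 to 7.79). The miR408 sum adds overlapping sequences (5 and 14, 11 and 20, 11 and 20 counts), so a read can count in more than one of them. None of these sequences exceeded 5.24 RPM. Measured by their highest single rows in each library, miR398 and miR408 fell below the minimum level and were not called. Compared with itself, osa-miR398a was 4.42-fold (1.76 to 12.0) higher with 8 and 15 reads, osa-miR398b had 1 and 26 reads (61.3-fold, 10.1 to 2515), and osa-miR408 was 4.29-fold (1.96 to 9.91) higher. With a pseudocount of 10 their log2 ratios were 0.96 and 0.89, under the limit, and miR408 was also not called when distinct tags were counted. miR397, also a regulator of copper proteins, had 4 reads in the susceptible library and none in the resistant one. The list median log2 ratio was 2.19, at percentile 95.6 of random lists, whose central range ran from -0.10 to 2.48. The random lists could hold the list's own members, and the upper end equals the log2 ratio of miR398. The percentile thus sets the list in part against itself. With a pseudocount of 10 the median was 1.25.

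The auxin list held families at both ends. The miR390 family sum was 3.62-fold higher in the resistant variety (1485 counts in the susceptible and 2280 in the resistant library, interval 3.39 to 3.87). Most of this sum came from sequences of the passenger arm, which overlap, so that a read can count in more than one of them. The guide strand osa-miR390, which triggers the trans-acting small RNAs that repress auxin response factors, had 17.4 and 222 RPM and was 12.7-fold higher (10.7 to 15.2). miR393, a regulator of auxin receptor genes, was 5.52-fold higher in the susceptible variety (268 against 48.5 RPM, interval 4.75 to 6.45). miR167, a regulator of auxin response factors, lay within 2-fold at 8129 and 10984 RPM (log2 ratio 0.43). Of the 4 families, 1 was higher in each variety and 2 lay within 2-fold. The list median was 0.32 and the mean 0.01, at percentile 74.6 for the median.

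In the developmental transcription factor list, 9 of 11 families lay within 2-fold. These are not all separate measurements. A sequence with 1401 and 772 counts, out of 1454 and 820 for miR157, was counted in miR156 too. miR165 reached the minimum level through passenger strands, and had 6.78 and 7.08 RPM without them. The miR169 family sum, whose guide strands target NF-YA transcription factor genes, had the highest ratio of all families at the minimum level. Its counts, which add overlapping sequences, were 111 in the susceptible and 631 in the shallower resistant library (13.4-fold, interval 10.9 to 16.6). Of these counts, 52 and 352 were passenger strands, and without them 59 and 279 counts were 11.2-fold higher (8.40 to 15.0), at 6.55 and 73.1 RPM. That guide sum still adds overlapping sequences, and the highest one, osa-miR169e, had 42 and 138 counts (7.75-fold, 5.45 to 11.2). miR159, which targets MYB transcription factor genes, was 2.08-fold higher in the susceptible variety (20799 against 9998 RPM, interval 2.06 to 2.10). miR172, a regulator of the APETALA family, had 884 and 457 RPM (log2 ratio -0.95). miR166, which targets homeodomain-leucine zipper genes, had 6914 and 3838 RPM (-0.85). miR156, a regulator of SPL genes, had 742 and 1135 RPM (0.61). The list median was 0.22, at percentile 80.4. The log2 ratio of miR156 to miR172, a pair tied to the passage from juvenile to adult growth, was -0.25 in the susceptible and 1.31 in the resistant library, a difference of 1.56.

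Families that target the silencing machinery itself lay within 2-fold. miR162, directed at a Dicer-like gene, had 33846 and 26821 RPM in the susceptible and resistant libraries (log2 ratio -0.34). Nearly all of this sum came from 2 overlapping sequences with nearly equal counts, and the higher one, osa-miR162a, had 17070 and 13527 RPM. miR168, directed at an ARGONAUTE gene, had 1801 and 996 RPM (-0.85). Their median was -0.59, without a percentile since only 2 families were measured. No family of the NLR-targeting list, named for immune receptor genes, reached the minimum level (0 of 9). Only 3 of the 9 were listed in either library, and why the rest had no row was not tested. Those listed had 2 and 1 reads (miR472), 1 and 3 reads (miR482), and 3 and 0 reads (miR2118), so a difference was not detectable for them at this depth. The monocot-restricted list had a single family at the minimum level, miR528, with 87.8 and 104 RPM (log2 ratio 0.25). Without a minimum level its median was -0.49, through miR444 (7 and 1 summed counts) and miR529 (23 and 1 summed counts). Outside the lists, miR1511 had 43.7 and 25.4 RPM (-0.76) and miR535 had 2185 and 1451 RPM (-0.59).

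**Figure D1:**
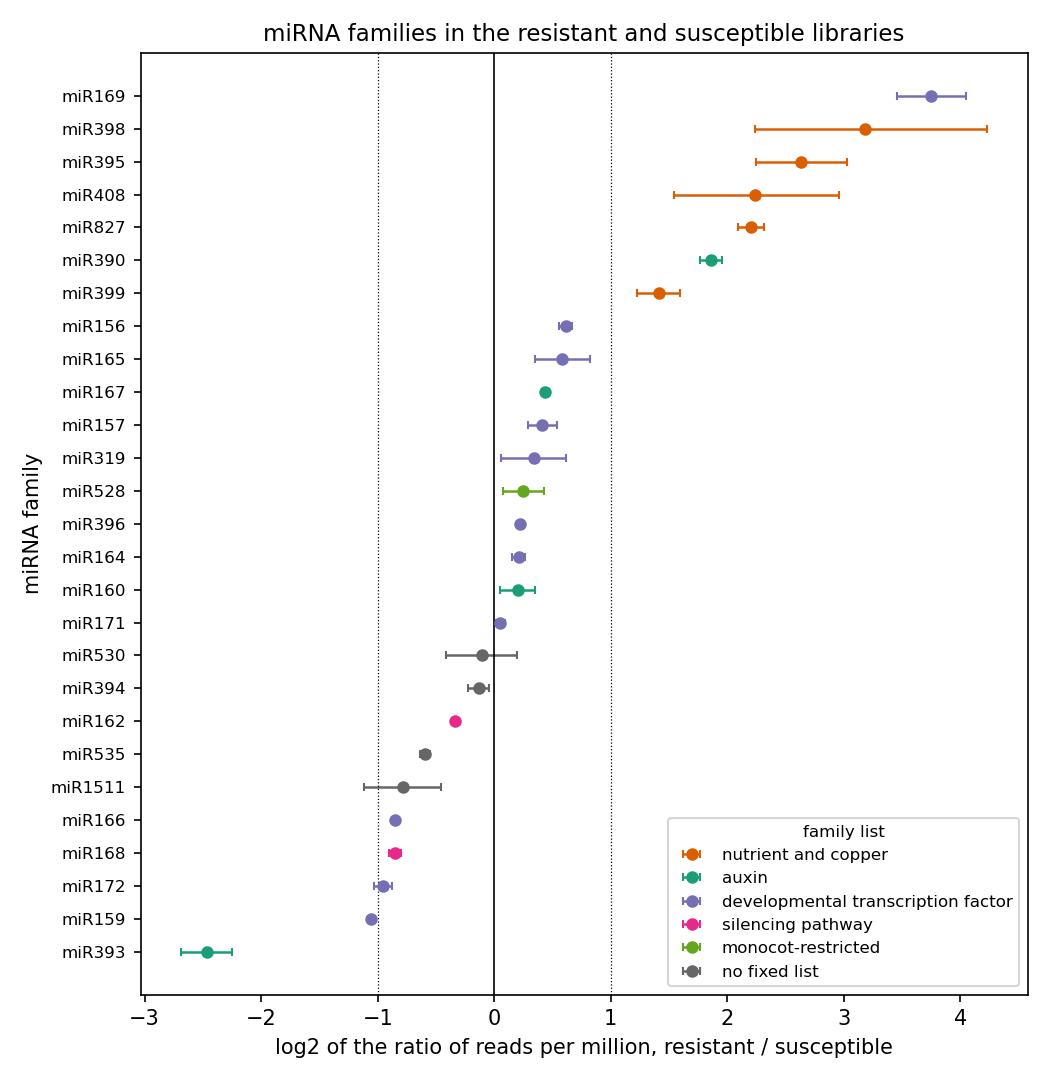
Ratio of resistant to susceptible RPM for the 27 families at the minimum level, on a log2 axis without a pseudocount; points are single libraries compared, bars are exact 95% counting intervals, colours mark the lists, and dotted lines mark 2-fold. All 5 nutrient and copper families lie beyond the right dotted line, and miR393 and miR159 lie beyond the left one.

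The libraries were dominated by the same families. Family sums can count a read in several overlapping sequences: distinct mature sequences summed to 1491890 and 616439 counts, and distinct tags to 1044734 and 438021 reads. miR396, which targets growth-regulating factor genes, was the most abundant, at 86318 RPM in the susceptible and 100613 RPM in the resistant library (log2 ratio 0.22). It made up 52.0% of the summed family counts in the susceptible library (exact interval 51.9% to 52.1%) and 62.2% in the resistant library (62.1% to 62.3%). The 5 most abundant families of both libraries were miR396, miR162, miR159, miR167 and miR166, with 94.0% and 94.1% of the sums.

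Single mature sequences of a family did not always share the family's ratio. Their counts are those of rows, which can hold other tags. The most abundant tag equalled the named mature sequence in 152 of 503 rows (susceptible) and 147 of 537 rows (resistant). Within miR396, osa-miR396a (UUCCACAGCUUUCUUGAACUG) had 50270 RPM in the susceptible and 75667 RPM in the resistant library, whereas osa-miR396d (UCCACAGGCUUUCUUGAACUG) had 23906 and 9413 RPM, 2.54-fold higher in the susceptible variety. Within miR159, ahy-miR159 (UUUGGAUUGAAGGGAGCUCUA) was 2.94-fold higher in the susceptible variety, at 15185 against 5159 RPM, and sbi-miR159b (CUUGGAUUGAAGGGAGCUCCU) had 940 and 1854 RPM. Within miR393, osa-miR393b (UCCAAAGGGAUCGCAUUGAUCU) had 1273 and 22 reads, 24.5-fold higher in the susceptible variety (interval 16.1 to 39.3), and osa-miR393 (UCCAAAGGGAUCGCAUUGAUC) was 2.60-fold higher there. Within miR390, osa-miR390 (AAGCUCAGGAGGGAUAGCGCC) was 12.7-fold higher in the resistant variety, and gma-miR390a-3p (CGCUAUCCAUCCUGAGUUUC), from the passenger arm, was 2.56-fold higher. Most abundant tags listed in both libraries gave other folds for some of these. The miR390 tag of the passenger arm had 623 and 440 reads, 1.67-fold higher in the resistant variety (1.47 to 1.89). No such tag matched osa-miR393b, and the miR393 tags were 3.52-fold and 2.49-fold higher in the susceptible variety. Tags identical to osa-miR390, osa-miR396d and ahy-miR159 kept their directions, at 12.5-fold, 2.54-fold and 3.08-fold. Mature sequences listed by family gave 97 entries at the minimum level, of which 15 were higher in the resistant and 10 in the susceptible variety. A sequence named under both miR156 and miR157 was counted in each, and it lay within 2-fold.

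**Figure D2:**
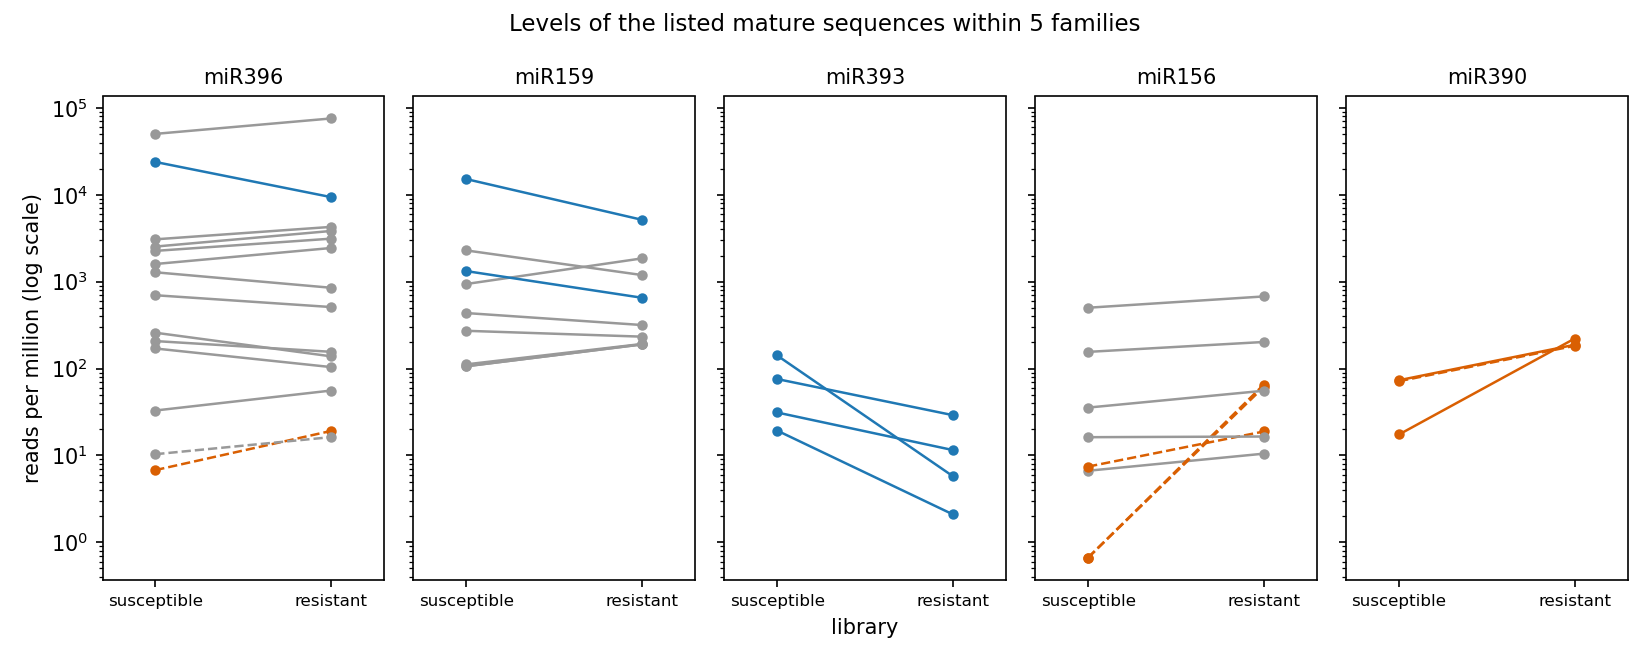
RPM on a log axis of the listed mature sequences of miR396, miR159, miR393, miR156 and miR390 whose higher level was at least 10 RPM. Each line joins the values of a sequence in the susceptible and resistant libraries. Orange marks sequences at least 2-fold higher in the resistant library, blue those at least 2-fold higher in the susceptible library, and grey the rest. Dashed lines are passenger strands named with an asterisk, and gma-miR390a-3p, from the passenger arm, is drawn solid. The miR393 lines all run down to the resistant library, and osa-miR396d runs down from 23906 to 9413 RPM beside osa-miR396a.

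In presence, 34 of 38 families were listed in both libraries. Listed in the susceptible library only were miR1318 (8 reads), miR397 (4 reads) and miR2118 (3 reads). In the resistant library only, miR829 was listed with 2 reads. If the RPM were equal in both libraries, all reads of miR1318, miR397 and miR2118 would fall in the susceptible library with a chance of 5.92%, 24.3% and 34.6%, and those of miR829 in the resistant library with a chance of 8.86%. These chances cover counting error alone, for families picked because the other library had 0 reads, so a difference in presence was not detectable at this depth.

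The authors' predicted miRNAs came to 9 distinct sequences of 18 to 28 nt, of which 3 were listed in both libraries, 4 in the susceptible library only and 2 in the resistant library only. The lowest listed count was 9, so the tables could carry a minimum, and no fold is given for a sequence listed once. TTCATGGACGTTGATAAGATCCTTC was listed in the resistant library only, with 488 reads (128 RPM), as was ATCACACATACAGTCATACTCAATTCGA with 14 reads. ATTGAGCCGCGCCAATATC (20 reads), ATCTTGATGATGCTGCAT (16 reads), CATCATTGAGTGCAGCGTTGA (10 reads) and CTGGCTCCCTGTATGCCA (10 reads) were listed in the susceptible library only. Among the shared sequences, CGATCATCAGATTATAAGTTCATTCC had 23 and 31 reads, 3.18-fold higher by RPM in the resistant library (interval 1.79 to 5.71). TCTGCCCTCCCTCTCTATC had 158 and 82 reads, with a fold of 1.22 (0.926 to 1.61), and ATAGGCAGTCTCCTTGGCTA had 9 and 9 reads, with a fold of 2.36 (0.830 to 6.71). Both of these intervals include 1-fold.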

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

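No paired analysis or leaving out of a library was possible with 1 library per group. The settings that count distinct tags, leave out passenger strands, scale to the summed family levels or keep mature sequences found in both libraries were chosen after seeing the data. None of the 18 families named for ratio or abundance changed sign across 10 settings. Pseudocounts and rescaling (shifts up to 0.20) could not reverse any. Comparison values moved as follows, the cause untested except where the setting itself shows it. With a pseudocount of 10 the nutrient and copper median was 1.25, and miR398 and miR408 were no longer called, as a larger pseudocount shrinks ratios of low levels. With no minimum level 4 families were higher in the susceptible variety (miR529 and miR828 added), and the monocot-restricted median reversed to -0.49, since 3 families then counted in place of 1. With a minimum of 100 RPM 4 were higher in the resistant variety, fewer families being eligible. Centring on the median ratio gave 5 higher in the susceptible variety and medians of 0.11 (auxin), 0.018 (developmental), -0.80 (silencing) and 0.043 (monocot-restricted). Scaling to summed family levels gave 0.26 (developmental) and -0.56 (silencing). A 1.5-fold limit gave 7 higher in the susceptible variety, and a 4-fold limit gave 4 in the resistant and 1 in the susceptible variety, by construction. The highest single row per family in each library, which can be different sequences, gave medians of 0.47 (auxin) and 0.28 (developmental). The miR156 to miR172 difference was 1.36 with the highest row, 1.42 with all rows, 1.26 with distinct tags and 1.38 without passenger strands. Under these settings, in that order, the miR396 share was 49.9%, 44.5%, 62.6% and 52.3% in the susceptible library, and 67.4%, 47.1%, 72.7% and 62.5% in the resistant library. Counting rows of at least 10 RPM left 2 families in the resistant library only and 0 in the susceptible library only. By exact name 470 were in both, 67 in the resistant and 33 in the susceptible library only, and by mature sequence 197, 35 and 23, since names and sequences outnumber families. Of the recomputed comparison values, 79 stayed within their counting interval or, for a number of families, within 1.5 times the reported one, 35 moved and 1 reversed. Within that limit, the families higher in the resistant variety numbered 5 (pseudocount 10, highest row), 6 (distinct tags) and 8 (1.5-fold limit) in place of 7, and those listed in both libraries numbered 23 (rows of at least 10 RPM) in place of 34. Matching predicted miRNAs by name was not run, as the tables used give them no names, and the NLR-targeting list had no value at the minimum level. Depth limits families under 10 RPM most, where 1 read was 0.111 or 0.262 RPM.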

Other observations

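The tests in this part were chosen after the result was seen, except the centring of ratios on their median, which was an alternative fixed before the data were examined. Passenger strands, the partner of the mature strand in the miRNA duplex, were taken here as rows whose names carry an asterisk, which leaves out forms named by arm such as gma-miR390a-3p. They made up 0.482% of the summed family counts in the susceptible and 0.568% in the resistant library. Those of miR169, a part of the miR169 family sum, had 5.78 and 92.3 RPM. Those of miR166 had 630 and 376 RPM, and those of miR390 had 74.1 and 188 RPM. Below the minimum level, miR828 had 34 summed counts in the susceptible and 2 in the resistant library, and miR529 had 23 and 1. miR858 had 14 and 4 reads, and miR2916 had 9 and 11.

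The nutrient and copper families were higher in the resistant variety in 5 of 5 cases at the minimum level. Of these, miR395, miR398 and miR408 reached that level in the resistant library only, and miR398 and miR408 did so only as sums over sequences. Below the minimum level, miR397 of the same list was listed in the susceptible library only, with 4 and 0 reads, a difference not detectable at this depth. The predicted sequence CATCATTGAGTGCAGCGTTGA, which shares a 17 nt run with miR397, was also listed in the susceptible library only, with 10 reads. A single scaling factor was argued against by a median log2 ratio of 1.99 after centring on all families. For counting noise, the sequences with the most reads in either library were each compared with themselves. Their intervals all lay above 1-fold in 5 of the 5 families. However, the miR408 tag listed in both libraries had 6 and 6 reads, 2.36-fold with an interval of 0.63 to 8.82. Counting noise was thus argued against for miR395, miR398, miR827 and miR399, and stays open for miR408. The intervals treat reads as independent molecules, which the protocol does not assure. A different proportion of leaf and root in the pools could also give such a pattern, and with 0 libraries of one organ alone it cannot be told apart from a difference between varieties. The variety itself, and any difference in nutrient supply or state between the plants, stay open and untested.

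One miR156 passenger sequence differed far more than the miR156 family. Its tag GCTCACTTCTCTCTCTGTCAGC, listed under zma-miR156a*, zma-miR156d* and other names, had 6 reads in the susceptible and 233 in the resistant library, and was 91.6-fold higher (interval 41.5 to 252). Another miR156 passenger sequence, zma-miR156e*, had 67 and 72 reads and was 2.54-fold higher. A general gain of passenger strands stays open as a part of the difference, because the values were mixed. Of 8 passenger forms from 6 other families, 6 had a log2 ratio above 0, with a median of 1.0004 and a range from -1.08 to 3.45. These forms include overlapping sequences of miR169 and of miR396. Summed over all families, passenger strands had 800 and 919 RPM (1.15-fold), the largest part being miR166 with 630 and 376 RPM. A sequence difference between the AAA and AAB genotypes, or a precursor expressed mainly in one variety, may account for the miR156 difference as a hypothesis, and neither was tested.

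Some predicted miRNAs may be shifted or trimmed forms of known families. Of the 9 sequences, 5 shared a run of at least 17 nt with a listed known sequence or tag (miR171, miR172, miR397, miR160 and miR169), longer than in any of 1000 shuffled copies of each, whose longest runs were 10 to 12 nt for these 5. The other 4, among them the sequence with 488 reads in the resistant library, shared at most 8 nt, which argues against this origin for them with respect to the 435 listed sequences searched. A biological explanation for those 4 was not tested.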
